A study of Rattus norvegicus with 24 samples.

How the data were processed

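Total RNA was extracted with Trizol from the dorsal horn of the operated side, made into biotinylated cRNA from 5 ug of RNA and hybridised to Affymetrix Rat Expression 230A arrays, per the labels' protocols. The values deposited by the authors are log2 expression per probe set. They were made with GCRMA, which corrects the background by probe sequence, normalizes across arrays and summarises probes, per the submitters' processing notes; its version is not given in the sources used here. The deposited log2 values were used as they stand, with no further transformation. GCRMA places the dim arrays of a probe set at a common low value. This value differs between probe sets, 2.09 log2 at the lowest and 3.39 log2 for Ly86 on all neonate sham arrays. Values near it carry little information on differences, and fold changes that start there are understated or depend on the background model.

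The data held 15923 probe sets on 24 arrays, and every column was matched to one sample by its label. Removing 57 control probe sets left 15866, of which 12783 had 1 gene symbol, 312 had several and 2771 were unnamed. Symbols came from the platform annotation, and 12754 of the probe sets with 1 symbol were matched to the list of rat genes, which changed 0 symbols. A listed symbol that another rat gene now bears was not matched through a synonym, except for a haemoglobin chain. No coordinates are given because the genome build of the arrays is not given in the sources used here. Probe sets with several symbols were tested but not named.

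The 4 groups of 6 arrays entered a linear model per probe set in limma 3.58.1 (R 4.3.3, package data.table at version 1.17.8), with a mean for each group, 20 residual degrees of freedom and moderated variances (prior degrees of freedom 3.81). The contrasts were SNI minus sham in adults, the same in neonates, the difference of those effects, and adult minus neonate sham. Probe sets were tested if they lay above the 40th percentile of all values, 3.84 log2, on at least 6 arrays, which kept 9638 probe sets and 7006 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. For gene-level results the probe set with the highest mean represented its gene. The labels describe the arrays of a group as biologically independent. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

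Before the data were examined, the tests, the filter, the processing alternatives, 32 gene lists of cell types and pathways and the rule for named genes were fixed. The rule named the 12 highest and 8 lowest fold changes of each contrast that passed the test without overlap between the 6 and 6 arrays (no condition on overlap for the difference between ages), up to 4 members with the smallest p in each list described, and a set of index genes of glia, neurons, lymphocytes and complement. Lists with at least 5 measured genes, 28 of the 32, were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list. With the estimated correlation 8, 6, 5 and 5 lists passed in the contrasts adult injury, neonate injury, difference between ages, and age in sham, of 14, 16, 11 and 12 with the preset one. Fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, was run beside it. Lists can share genes, such as C3 in the complement and reactive astrocyte lists. Means over a list were compared by two-sided exact permutation tests, which cannot go below p = 0.0022 with 6 against 6 arrays. For the difference between ages, the SNI minus sham differences of same-numbered arrays were exchanged between the ages, a test chosen after the data had been seen because exchanging injury labels within an age would put the injury effects into the reference distribution. That first exact permutation test had given two-sided p = 0.0728 for the microglia list and p = 0.205 for its 16 genes above the filter level on all arrays.

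The replicate numbers in the labels were checked for pairing. Deviations of arrays from their group means correlated between same-numbered sham and SNI arrays at 0.10 to 0.56 in adults and 0.24 to 0.61 in neonates, all above 0.1, and averaged 0.352 over all same-numbered arrays of different groups against -0.068 for arrays of different number. The numbers were therefore taken to pair sham and SNI arrays within an age, although the labels do not say what a number stands for, and fits with the number as a block were made as an alternative. Across ages the lowest such correlation was 0.014, and the arrays were not taken as paired. However, 33 of all 36 same-numbered pairs of different groups exceeded 0.1. Arrays numbered 5 and 6 in different groups also correlated at 0.306 on average. What a number marks is therefore not settled, and the pairing within an age is an assumption. The first 3 principal components held 35.0%, 14.3% and 10.0% of the variance, and on the second component the 4 arrays numbered 3 lay apart, at -17.3 or below against -8.20 or above for all others. RNA integrity was compared by the 3' minus 5' difference of the actin and Gapdh control probe sets, and the lowest exact permutation p between sham and SNI was 0.0736 (neonate actin, adjusted p = 0.294). With SNI and sham exchanged within same-numbered pairs, a test added after the data had been seen, the neonate actin difference was lower after SNI in 6 of 6 pairs (mean -0.13 log2, two-sided exact permutation p = 0.0312, adjusted p = 0.125 over 4 tests), so a shift of RNA quality with neonate injury is not excluded.

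The calculation was tested on simulated data with 9638 probe sets. With true changes of 0.5, 1 and 2 log2 in 67, 67 and 66 probe sets, it recovered 62.7%, 94.0% and 98.5% in adult injury, 56.7%, 95.5% and 100% in neonate injury, 32.8%, 83.6% and 95.5% for the difference between ages, and 61.2%, 94.0% and 98.5% for age in sham. False calls were 2.86%, 5.08%, 2.76% and 7.14% of all calls in these contrasts. Of 28 simulated lists, 3 shifted by 0.3 log2 were recovered in adult injury and 0 of the others were called. The simulated noise was independent between probe sets and arrays, and the lists were drawn at random. The simulation therefore does not show how camera behaves where the genes of a list are correlated, such as the ribosomal proteins (estimated correlation 0.516), or where arrays deviate by number. Alternatives tried were no filter or a filter at the 60th percentile, quantile normalization, median centring, an intensity trend with robust variances, array weights, only the 12 arrays of a comparison, the replicate block, leaving out each array in turn, a minimum log2 change of 1, 1 count per gene and the mean of a gene's probe sets. A block for each number within each age and a fit without the arrays numbered 3 were chosen after seeing the data. An alternative transformation planned for linear values was not run, because the values were already log2.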

Results

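Gene expression was measured in the dorsal horn of the rat spinal cord, the region where sensory fibres of the peripheral nerves end, on the side of an operated sciatic nerve. Sprague-Dawley rats received either spared nerve injury (SNI), in which the tibial and common peroneal branches were tied and cut while the sural branch was left whole, or a sham operation in which the nerve was only exposed. Tissue was studied 7 days after injury in adults aged 8 to 12 weeks and in neonates labelled postnatal day 10. The labels do not say whether day 10 was the age at surgery or at tissue collection. Each of the 4 groups (adult sham, adult SNI, neonate sham, neonate SNI) held 6 arrays described as biologically independent. The median log2 value per array ran from 5.56 to 5.66, between 59.7% and 60.4% of probe sets per array lay above the filter level of 3.84 log2, and the lowest correlation between any 2 arrays was 0.984. No pair of arrays held identical values. The number of arrays limits the precision of every value.

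In adults the comparison of SNI with sham asked which transcripts the nerve injury changed in the dorsal horn. The largest rises included a chemokine, complement proteins and immunoglobulin receptors. Cxcl13, a chemokine that attracts B cells, was at least 10.8-fold higher after SNI, with 7.27 ± 0.91 log2 (SD, n = 6) against 2.12 ± 0.061 in sham (limma adjusted p = 1.9e-13). The 3 chains of C1q, which starts the classical complement pathway, rose together: C1qc by 3.64 log2 (SE 0.28, adjusted p = 1.6e-09), C1qb by 3.16 log2 (SE 0.30, adjusted p = 8.3e-08) and C1qa by 2.66 log2 (SE 0.22, adjusted p = 4.8e-09). C3, the central complement protein, rose from 8.03 to 11.18 log2 (SE of the difference 0.31, adjusted p = 1.4e-07).

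The other leading genes included receptors and a transcription factor. The immunoglobulin receptors Fcgr3a and Fcgr2b were at least 4.35-fold and at least 2.70-fold higher (adjusted p = 3.5e-15 and 4.8e-13). Irf8, a transcription factor of the myeloid lineage, was at least 3.40-fold higher (adjusted p = 3.7e-11), Ly86, a partner of a Toll-like receptor homologue, at least 4.74-fold (adjusted p = 8.2e-14), and the C-type lectin Clec4a3 at least 2.99-fold (adjusted p = 4.1e-10). Plac8 rose by 4.42 log2 (SE 0.30, adjusted p = 2.5e-10). Reg3b, a secreted lectin that injured sensory neurons are known to express, was at least 3.81-fold higher (adjusted p = 0.00479) and lay above the filter level on 5 of the 6 SNI arrays. Each of these 12 genes had 6 of 6 SNI arrays above all 6 sham arrays, as the rule for naming them required. Wherever a change is given as at least N-fold, every array of the lower group lay below the filter level, and the mean of the higher group was set against that level.

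The list of microglia and macrophage genes had the most members that rose. Of 27 measured members 23 rose over all genes tested and 24 rose when adjusted over the list alone, with a median change of 1.55 log2, or 1.32 log2 with values under the filter level raised to it (camera adjusted p = 2.4e-86, adjusted p = 1.2e-08 with an estimated correlation). Aif1, the microglial calcium-binding protein also called Iba1, rose from 6.54 ± 0.23 to 8.68 ± 0.32 log2 (SD, n = 6; limma adjusted p = 2.2e-09), and the tetraspanin Cd53 rose by 2.07 log2 (adjusted p = 1.7e-10). The mean over the list rose from 5.91 ± 0.091 to 7.40 ± 0.15 log2 (SD, n = 6; exact permutation p = 0.0022, the smallest that 6 against 6 arrays allow, adjusted p = 0.0076 over 28 lists). Cx3cr1, the fractalkine receptor, rose by 1.63 log2 (SE 0.38, adjusted p = 0.0157), but its adjusted p was 0.0503, 0.0527 and 0.0544 without adult sham 2, adult SNI 5 and adult SNI 6 respectively. Only 1 of its 6 adult sham arrays lay above the filter level, so the size of this rise depends on the background model.

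**Figure D1:**
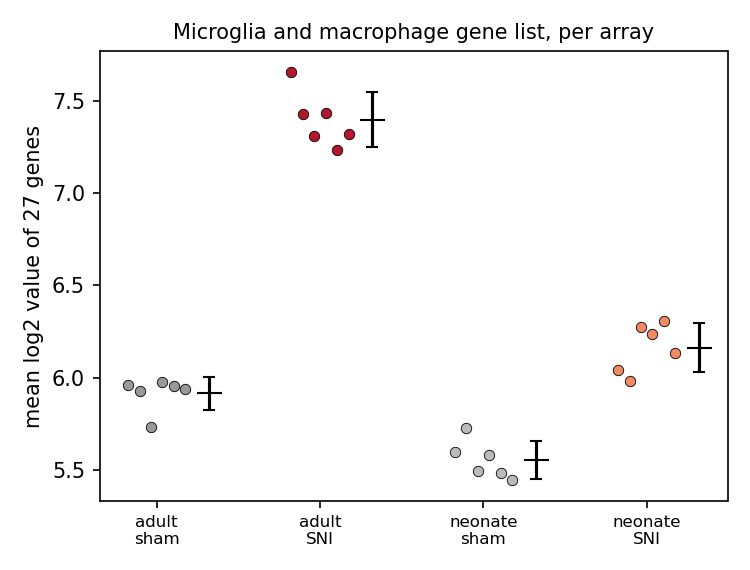
Mean log2 value over the 27 measured microglia and macrophage genes, one point per array, with the mean and SD of each group of 6 arrays. The adult groups averaged 5.91 in sham and 7.40 after SNI, and the neonate groups 5.55 in sham and 6.16 after SNI.

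Genes of antigen presentation, complement and cytokine signalling also rose in adults. In the MHC class II list 5 of 8 members rose over all genes and 8 when adjusted over the list alone (median 1.27 log2, camera adjusted p = 1.8e-21, adjusted p = 8.3e-05 with an estimated correlation). They included the lysosomal reductase Ifi30 by 1.56 log2, the peptide-loading chains RT1-DMb and RT1-DMa by 1.36 and 1.34 log2, and the protease Ctss by 0.91 log2. Cd74, the invariant chain of class II molecules, had a difference of 1.19 log2 (SE 0.39) with an adjusted p of 0.186. In the complement list 4 of 10 rose over all genes, the C1q chains and C3, and 5 when adjusted over the list alone (median 0.43 log2, camera adjusted p = 5.6e-19, adjusted p = 1.4e-04 with an estimated correlation). Of 18 measured cytokines, chemokines and their receptors 7 rose, and 9 when adjusted over the list alone (median 0.30 log2, camera adjusted p = 5.1e-13, adjusted p = 8.3e-05 with an estimated correlation). Il18 rose by 1.65 log2, the interferon gamma receptor Ifngr1 by 1.28 log2 and Cxcl16 by 0.92 log2. In the MHC class I list 3 of 10 rose under both adjustments, over all genes and adjusted over the list alone (median 0.39 log2, camera adjusted p = 5.3e-07, adjusted p = 0.00384 with an estimated correlation). The immunoproteasome subunit Psmb8 rose by 2.21 log2 and the proteasome activator Psme1 by 0.83 log2. The interferon response list had 3 of 12 higher, and 6 when adjusted over the list alone (median 0.44 log2, camera adjusted p = 2.2e-11, adjusted p = 0.00316 with an estimated correlation). Its leading members were Psmb8, the guanylate-binding protein Gbp2, at least 2.01-fold higher, and the nuclear body protein Sp110, which rose by 1.22 log2.

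Smaller changes reached glial and signalling genes. Of 14 reactive astrocyte genes 3 rose, and 5 when adjusted over the list alone (median 0.28 log2, camera adjusted p = 1.2e-07, adjusted p = 0.00271 with an estimated correlation): C3, the protease inhibitor Timp1 by 1.24 log2 and ceruloplasmin, Cp, by 0.51 log2, or 2.08 log2 with its dimmer probe set (adjusted p = 2.3e-05). Gfap, the astrocytic intermediate filament, differed by 0.34 log2 (SE 0.094, adjusted p = 0.0648). Of 15 immediate-early genes 1 rose, and 5 when adjusted over the list alone (median 0.28 log2, camera adjusted p = 2.1e-05, adjusted p = 0.00371 with an estimated correlation), namely the ERK phosphatase Dusp6 by 0.68 log2 (adjusted p = 0.00839), with 0.32 and 0.88 log2 in its other probe sets (adjusted p = 0.147 and 0.0200). The list of opioid, trophic and nociceptive signalling had 2 of 16 higher, and 3 when adjusted over the list alone. They were Tspo, a protein of the outer mitochondrial membrane, by 2.38 log2, and the neuropeptide precursor Vgf by 0.54 log2. The median of this list was -0.03 log2 and its mean 0.19 log2, so that they differed in sign (camera adjusted p = 0.0299, adjusted p = 0.0776 with an estimated correlation, and camera adjusted p = 0.117 without adult sham 4).

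Shifts of constitutive gene groups were small. The general astrocyte list shifted upward in camera by a median of 0.02 log2 over 27 genes (camera adjusted p = 0.0347, adjusted p = 0.351 with an estimated correlation). In this list 4 members rose when adjusted over the list alone and 0 over all genes in limma, against 4 at an unadjusted p under 0.05. The 29 ribosomal protein genes had a median of 0.11 log2 (camera adjusted p = 1.8e-06, adjusted p = 0.351 with an estimated correlation). Medians were -0.11 log2 for 44 genes of oxidative phosphorylation (camera adjusted p = 1.5e-05, adjusted p = 0.384 with an estimated correlation), -0.12 log2 for 20 genes of cholesterol synthesis (camera adjusted p = 0.0136, adjusted p = 0.351 with an estimated correlation) and -0.09 log2 for 31 pan-neuronal genes (camera adjusted p = 0.0179, adjusted p = 0.318 with an estimated correlation). Without adult sham 3 the median of the astrocyte list turned to -0.03 log2 (camera adjusted p = 0.142). Camera adjusted p reached 0.302 for astrocytes without adult SNI 4, 0.124 for pan-neuronal genes without adult SNI 2 and 0.0577 for cholesterol synthesis without adult SNI 3. The lists for oligodendrocytes and myelin, oligodendrocyte precursors, excitatory and inhibitory dorsal horn neurons, and GABA and glycine receptors had camera adjusted p of 0.862, 0.881, 0.297, 0.521 and 0.432. Those for glutamate receptors, voltage-gated ion channels, primary sensory neurons and motor neurons had 0.128, 0.0772, 0.0884 and 0.440. For Schwann cells, endothelial cells, fibroblasts, cell cycle and immature neurons the values were 0.981, 0.440, 0.440, 0.383 and 0.432. Gad1, the enzyme of GABA synthesis, Slc17a6, the vesicular glutamate transporter, and Mbp, myelin basic protein, differed by -0.17, -0.01 and 0.02 log2, with adjusted p of 0.877, 0.995 and 0.990. Mbp averaged 14.99 log2 in adult sham and 15.01 after SNI, near the highest values of the arrays, so saturation of its signal is not excluded.

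Over all 9638 probe sets tested, 193 changed in adults at an adjusted p under 0.05, 188 higher and 5 lower, and 84 of the higher ones changed at least 2-fold. With the replicate number as a block the count was 297 (264 higher, 33 lower), and with a separate block per age 291 (264 higher, 27 lower). A filter at the 60th percentile left 106. Of the 9638 probe sets, 172 had no overlap between the 6 and 6 arrays, against a chance share of 0.216%, and 149 of these were among the 193. The lower 5, described after their values were seen, included the fast-muscle troponin Tnnc2, which fell by 1.40 log2 (adjusted p = 0.00874), the cadherin Cdh22, which fell by 0.62 log2 (adjusted p = 0.0248) in 1 probe set and differed by -0.06 log2 in the brighter one (adjusted p = 0.989), and 2 probe sets with no gene name, which fell by 0.71 and 0.27 log2 (adjusted p = 0.0415 and 0.0296). The peptide hormone apelin, Apln, fell by 0.45 log2 (SE 0.10, adjusted p = 0.0163), with 6 of 6 SNI arrays below all sham arrays, as the naming rule required. Without adult sham 4 or adult SNI 6 Apln had differences of -0.39 and -0.41 log2 and adjusted p of 0.0566 and 0.0556. Cdh22 had adjusted p of 0.0703, 0.0708 and 0.0785 without adult sham 4, adult sham 5 and adult SNI 4. The 2 unnamed probe sets had adjusted p of 0.0503 to 0.122 without any 1 of 11 arrays and of 0.0506 to 0.0864 without any 1 of 7.

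**Figure D2:**
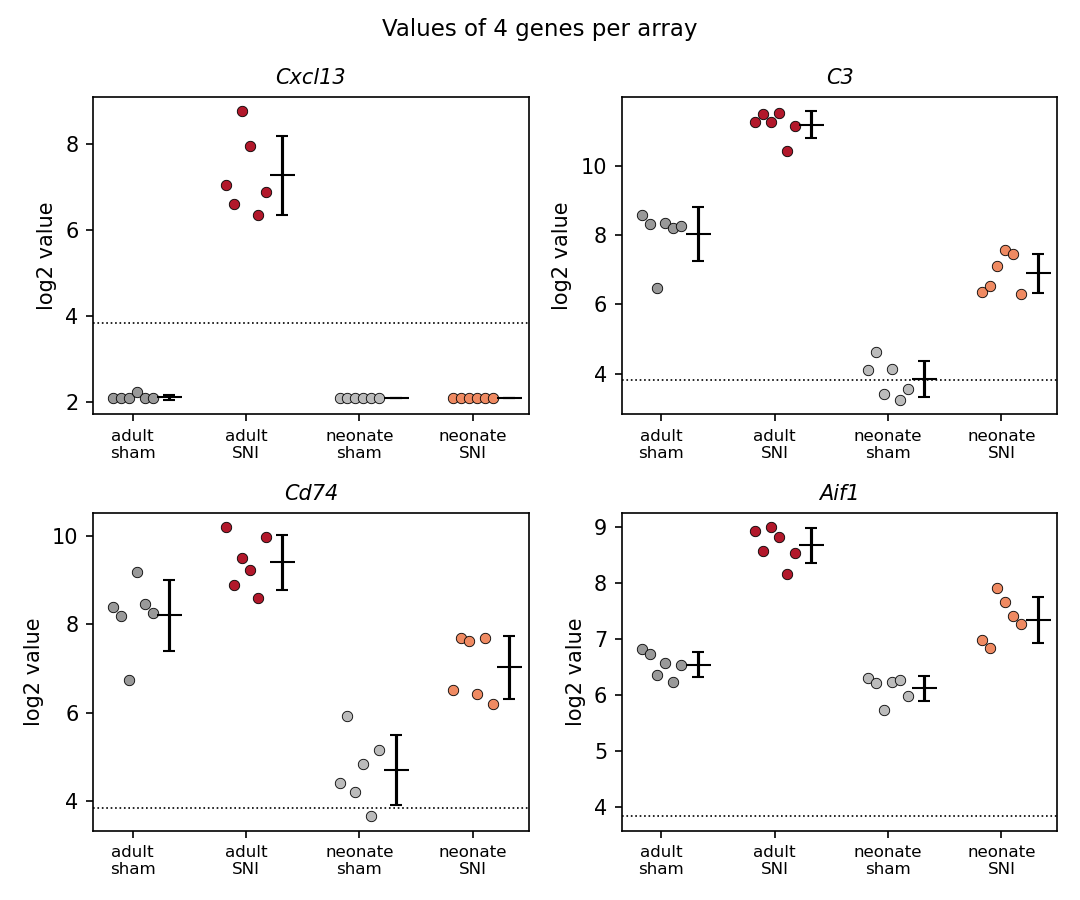
Log2 values of Cxcl13, C3, Cd74 and Aif1 on each of the 24 arrays by group, with group means and the filter level of 3.84 log2 as a dotted line. Cxcl13 averaged 7.27 after SNI in adults and lay at 2.09 in both neonate groups, while C3 averaged 6.89 after SNI in neonates against 3.85 in sham.

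In neonates the same comparison gave a shorter list led by complement and MHC class II genes. C3 rose from 3.85 to 6.89 log2 (SE of the difference 0.31, adjusted p = 7.9e-06). C1qc rose by 2.20 log2 (SE 0.28, adjusted p = 9.5e-05), C1qb by 2.13 log2 (SE 0.30, adjusted p = 3.1e-04) and C1qa by 1.88 log2 (SE 0.22, adjusted p = 2.9e-05). Cd74 rose from 4.70 to 7.02 log2 (SE of the difference 0.39, adjusted p = 0.00238), and the class II chain RT1-Da by 2.03 log2 (SE 0.41, adjusted p = 0.0186). Only 3 of 6 neonate sham arrays of C3 and 1 of 6 of RT1-Da lay above the filter level, so these 2 rises may be understated. Microglial and macrophage genes rose by smaller amounts, with Aif1 at 1.22 log2 (SE 0.17, adjusted p = 2.0e-04), the perforin-like Mpeg1 at 1.12 log2 (adjusted p = 0.00347) and the Fc receptor chain Fcer1g at 1.08 log2 (adjusted p = 0.00472). Plac8 was at least 1.64-fold higher (adjusted p = 2.0e-04), the lysosomal protease Ctsz rose by 1.44 log2 (adjusted p = 0.00238) and the lectin galectin-3, Lgals3, by 1.10 log2 (adjusted p = 0.0317). All 12 of these genes had 6 of 6 SNI arrays above all 6 sham arrays, as the rule for naming them required.

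Of the 27 microglia and macrophage genes 10 rose in neonates over all genes and 16 when adjusted over the list alone (median 0.47 log2, or 0.39 log2 with values under the filter level raised to it, camera adjusted p = 6.6e-53, adjusted p = 8.5e-07 with an estimated correlation). They included Cd53 at 0.97 log2, the colony-stimulating factor receptor Csf1r at 0.99 log2, and the signalling adaptor Tyrobp, at least 1.32-fold higher. The mean over the list rose from 5.55 ± 0.10 to 6.16 ± 0.13 log2 (SD, n = 6; exact permutation p = 0.0022, adjusted p = 0.0152 over 28 lists). In the complement list 4 of 10 rose, and 6 when adjusted over the list alone (median 0.54 log2, camera adjusted p = 7.6e-23, adjusted p = 7.9e-05 with an estimated correlation). In the MHC class II list 3 of 8 rose, and 6 when adjusted over the list alone (median 0.53 log2, camera adjusted p = 2.3e-19, adjusted p = 1.7e-04 with an estimated correlation). Of the reactive astrocyte genes 2 of 14 rose, C3 and Timp1, and 5 when adjusted over the list alone (median 0.28 log2, camera adjusted p = 2.4e-12, adjusted p = 1.8e-04 with an estimated correlation), while Gfap differed by 0.31 log2 (adjusted p = 0.482). Of the cytokine list 1 of 18 rose, Ifngr1, and 2 when adjusted over the list alone (median 0.15 log2, camera adjusted p = 1.8e-04, adjusted p = 0.0230 with an estimated correlation).

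The MHC class I and interferon response lists shifted upward in neonates as sets (medians both 0.15 log2, camera adjusted p = 3.2e-04 and 2.6e-05, adjusted p = 0.0486 and adjusted p = 0.0647 with an estimated correlation). Single members passed limma's test over all genes in 0 of 10 and 0 of 12 cases, and in 0 cases adjusted over the list alone, against 3 and 2 at an unadjusted p under 0.05. Ribosomal protein genes had a median of 0.10 log2 (camera adjusted p = 1.6e-07, adjusted p = 0.234 with an estimated correlation), primary sensory neuron genes 0.38 log2 (camera adjusted p = 0.0236, adjusted p = 0.234 with an estimated correlation), the Schwann cell list 0.40 log2 (camera adjusted p = 0.00629, adjusted p = 0.234 with an estimated correlation) and the fibroblast list 0.08 log2 (camera adjusted p = 0.00208, adjusted p = 0.416 with an estimated correlation). Without neonate sham 3, whose Schwann cell list mean was 7.16 log2 against 8.75 on the 5 other sham arrays, the medians of the Schwann cell and fibroblast lists were -0.02 and -0.04 log2 (camera adjusted p = 0.347 and 0.906). Endothelial genes had a median of -0.10 log2 (camera adjusted p = 0.00156, adjusted p = 0.120 with an estimated correlation) and ion channels -0.09 log2 (camera adjusted p = 0.0113, adjusted p = 0.215 with an estimated correlation). Glutamate receptors, cholesterol synthesis and pan-neuronal genes had medians of -0.10, -0.09 and -0.05 log2 (camera adjusted p = 0.0168, 0.0113 and 0.0134, adjusted p = 0.234, 0.296 and 0.234 with an estimated correlation). Leaving out 1 array also ended the camera calls of sensory neuron genes (median 0.14 log2, adjusted p = 0.263 without neonate SNI 1, and medians of 0.21 to 0.24 log2 without neonate SNI 3 or 4 or neonate sham 6), ion channels and glutamate receptors (0.179 and 0.246 without neonate SNI 3), cholesterol synthesis (0.114 without neonate SNI 5) and pan-neuronal genes (0.172 without neonate sham 3). Medians were -0.04 log2 for cholesterol synthesis without neonate sham 1 or 4, -0.05 log2 for glutamate receptors without neonate sham 5 and -0.03 log2 for pan-neuronal genes without neonate SNI 5.

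In total 30 probe sets rose in neonates and 0 fell in limma, against 166 higher and 74 lower at an unadjusted p under 0.05. There were 45 probe sets with no overlap between the groups (chance share 0.216%), 26 of them among the 30. With only the 12 neonate arrays in the fit 18 probe sets changed. Several neonatal calls lay close to the threshold and were lost with little change in the fold. RT1-Da had differences of 1.88 to 2.00 log2 and adjusted p between 0.0538 and 0.0688 when neonate sham 3, 4, 5 or 6 or neonate SNI 2, 3 or 5 was left out, and Lgals3 0.98 to 1.10 log2 and adjusted p between 0.0674 and 0.127 without neonate sham 3, 4, 5 or 6 or neonate SNI 1, 3 or 5. Ctss, 1 of the 3 MHC class II genes, passed at 0.0481 and had 0.52 to 0.62 log2 and 0.0501 to 0.171 without any 1 of 19 arrays, which were all but adult sham 3 and 4, adult SNI 1, neonate sham 2 and neonate SNI 2. Ifngr1 passed at 0.0481 and had 0.58 to 0.69 log2 and 0.0513 to 0.171 without any 1 of 20 arrays, which were all but adult sham 1 and 2 and neonate sham 1 and 2. Timp1 passed at 0.0498 and had 0.69 to 0.80 log2 and 0.0513 to 0.190 without any 1 of 18 arrays, which were all but adult sham 4, adult SNI 1 and 2, neonate sham 1 and neonate SNI 5 and 6.

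The crossed design allowed a direct test of whether the injury effect differed with age. It differed for 22 probe sets, in each case with the larger fitted rise in adults, and 0 with the larger rise in neonates in limma, against 190 and 48 at an unadjusted p under 0.05. A filter at the 60th percentile, which removes dim probe sets, left 6. Among genes measured above the filter level on all 24 arrays, the protease inhibitor Serpinb1a rose from 4.65 to 6.98 log2 in adults and differed by 0.20 log2 in neonates (difference of effects 2.14 log2, SE 0.15, adjusted p = 9.2e-10). Its adult sham arrays other than adult sham 4 averaged 4.68 log2 with an SD of 0.0087, so a low value of its own above the level is not excluded. Tspo showed a difference of effects of 1.86 log2 (SE 0.30, adjusted p = 0.00187) and Ifi30 of 0.99 log2 (SE 0.19, adjusted p = 0.0178). Cxcl13 lay at the lowest value of the table, 2.09 log2, on every neonate array, and Fcgr3a, Ly86, Fcgr2b, Irf8, Clec4a3, Rac2 and Pycard also lay below the filter level on all 12 neonate arrays, so that no fold change is given for them in neonates. The tests of these 8 differences had adjusted p of 5.4e-10, 2.4e-11, 5.4e-10, 1.5e-07, 2.4e-06, 5.8e-04, 8.7e-04 and 0.00206. These p-values depend on the background model, because a neonate rise below the level would not be seen. Cxcl13 had an SD of 0 log2 in both neonate groups, which also lowers the spread shared by the 4 groups. Plac8 rose at both ages, and the test of its difference had an adjusted p of 0.0178, but its neonate sham arrays all lay below the filter level, so the neonate rise is known only as a lower bound. Cd53, singled out after its values were seen, rose at both ages and more in adults (1.10 log2, adjusted p = 0.00649). The tetraspanin Cd37 had a difference of 1.55 log2 (SE 0.19, adjusted p = 2.2e-05), but only 3 of its 6 neonate sham arrays lay above the filter level.

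The effects of several leading genes were not shown to differ with age. For C3 the difference of effects was 0.11 log2 (SE 0.44, 95% interval from -0.80 to 1.02), for C1qb 1.02 log2 (SE 0.43) and for Cd74 -1.13 log2 (SE 0.55), each with an adjusted p of 1.00, and for Aif1 0.91 log2 (SE 0.24, adjusted p = 0.185). Only 3 of the 6 neonate sham arrays of C3 lay above the filter level, so its neonate rise may be understated and equal effects are not shown. As a set, the microglia and macrophage genes rose more in adults: 6 of 27 differed over all genes and 19 when adjusted over the list alone (median difference 0.78 log2, camera adjusted p = 2.2e-51, adjusted p = 1.1e-06 with an estimated correlation). The list mean rose by 0.87 log2 more in adults (95% interval 0.67 to 1.08, exact permutation p = 0.0022 for the differences of same-numbered arrays exchanged between ages, adjusted p = 0.0303 over 28 lists). Larger adult effects were also found by camera for cytokines and their receptors (1 of 18 over all genes, Cxcl13, and 4 adjusted over the list alone; median 0.23 log2, adjusted p = 1.1e-08, adjusted p = 0.00126 with an estimated correlation) and MHC class II genes (1 of 8, Ifi30, and 3 adjusted over the list alone; median 0.58 log2, adjusted p = 2.3e-06, adjusted p = 0.0388 with an estimated correlation). The opioid and trophic list (1 of 16, Tspo, and 2 adjusted over the list alone; median 0.08 log2) had a camera adjusted p = 0.00382 and an adjusted p = 0.0388 with an estimated correlation, and immediate-early genes (median 0.16 log2) had 0.00328 and an adjusted p = 0.0498 with an estimated correlation. The list means of class II, opioid and immediate-early genes rose by 0.31, 0.16 and 0.18 log2 more in adults. Exact permutation gave these adjusted p of 0.634, 0.136 and 0.25, so it did not show a larger adult effect. Of the 8 class II genes 6 rose more in adults, but Cd74 did not, nor did RT1-Da (1.42 log2 in adults, 2.03 in neonates).

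Further lists passed camera for the difference of effects without passing when the correlation was estimated. Medians were 0.17 log2 for complement (camera adjusted p = 3.3e-04, adjusted p = 0.0995 with an estimated correlation), 0.24 log2 for interferon response (camera adjusted p = 1.5e-05, adjusted p = 0.0592 with an estimated correlation), 0.14 log2 for MHC class I (camera adjusted p = 0.00342, adjusted p = 0.101 with an estimated correlation) and 0.12 log2 for endothelial genes (camera adjusted p = 0.00345, adjusted p = 0.148 with an estimated correlation). Fibroblast genes (median -0.16 log2, camera adjusted p = 0.00328) and oxidative phosphorylation genes (median -0.10 log2, camera adjusted p = 0.00101) both had an adjusted p = 0.634 with an estimated correlation. Without neonate sham 3 the fibroblast list had a median of -0.08 log2 and a camera adjusted p of 0.297.

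**Figure D3:**
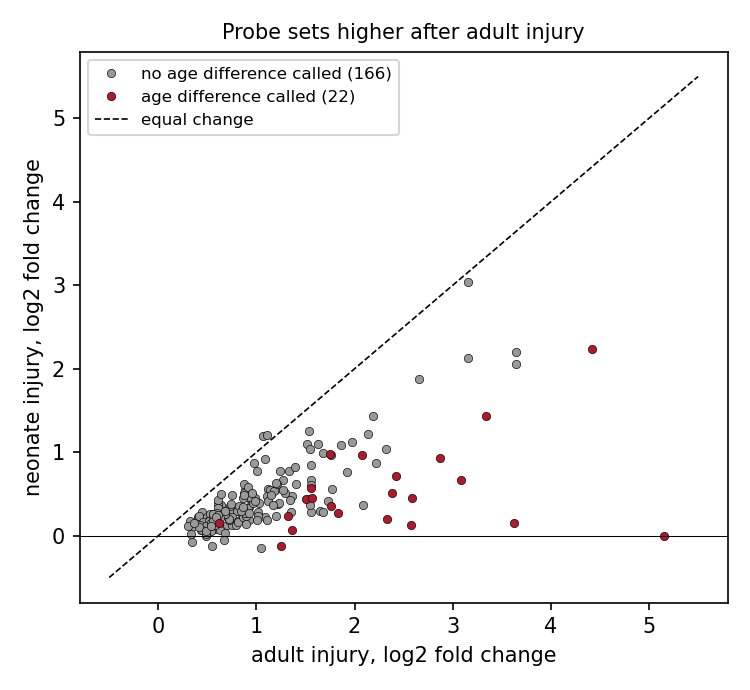
Neonate against adult log2 fold change (SNI minus sham) of the 188 probe sets that rose in adults, with a dashed line of equal change. The 22 probe sets whose effect differed with age are in red and the other 166 in grey. Of the 188, 186 had a smaller change in neonates, where the median was 0.30 log2 against 0.92 log2 in adults.

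Most of the genes that rose in neonates also rose in adults. Of the 30 probe sets higher in neonates 27 were among the 188 higher in adults, where independent lists would share 0.585. The other 3 were Cd74, RT1-Da and Lgals3, with adult differences of 1.19, 1.42 and 0.69 log2 (adjusted p = 0.186, 0.0876 and 0.195). Of the 188 probe sets higher in adults 183 had a change above 0 in neonates, and in 186 it was smaller than in adults, which favours adults in part because the set was chosen on the adult values. The medians were 0.92 and 0.30 log2, or 0.89 and 0.26 log2 with values under the filter level raised to it. Across 7006 genes, which are not independent replicates, the adult and neonate changes had a Pearson correlation of 0.580, larger than in all 100 permutations of the injury labels within age (highest 0.561, permutation p = 0.0099, the smallest they can give). Spearman's correlation was 0.299, within the range of the permutations, -0.540 to 0.514 (permutation p = 0.188). With SNI and sham exchanged within same-numbered pairs, a test added after the data had been seen, the two-sided exact permutation p was 9.8e-04 for Pearson's correlation, the smallest possible, and 0.0225 for Spearman's. Leaving out the array neonate SNI 3 gave a Pearson correlation of 0.459.

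Sham animals of the 2 ages were compared to show the background on which injury acted. Among the genes with the largest differences, C3 was higher in adults by 4.17 log2 (SE 0.31, adjusted p = 1.3e-09), Cd74 by 3.51 log2 (SE 0.39, adjusted p = 8.3e-07) and RT1-Da by 3.33 log2 (SE 0.41, adjusted p = 3.1e-06). Alas2, the first enzyme of haem synthesis in red cells, was higher by 4.18 log2 (SE 0.54, adjusted p = 5.2e-06), the haemoglobin chains Hba-a3 and Hbb by 2.82 and 2.20 log2, and platelet factor Pf4 by 2.52 log2 (SE 0.52, adjusted p = 0.00123). Signalling and metabolic genes higher in adults included Rasgrp3, an activator of Ras, by 3.15 log2, the phosphatase inhibitor Ppp1r1b by 2.81 log2, D-amino acid oxidase, Dao, by 2.64 log2 and the retinaldehyde dehydrogenase Aldh1a1 by 2.59 log2. Tnnc2 was higher by 2.82 log2, and Smim5 at least 3.21-fold. For C3, RT1-Da, Pf4 and Dao only 3, 1, 2 and 1 of the 6 neonate sham arrays lay above the filter level, so these differences may be understated.

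Among the genes lower in adult than in neonate sham, the calcium-sensing receptor Casr was at least 3.77-fold and the carbonic anhydrase Car3 at least 3.69-fold lower (adjusted p = 6.2e-11 and 5.2e-10). The lipase Pnlip fell by 2.97 log2 (SE 0.16, adjusted p = 4.9e-12), the ketone body enzyme Bdh1 fell by 2.17 log2 and the receptor phosphatase Ptpro fell by 2.17 log2. Tcf7l2, a transcription factor of the Wnt pathway, fell by 2.13 log2, and the GTPase Rras2 and Dpysl4, a protein of axon growth, both fell by 2.03 log2. The 20 genes named so far in this comparison other than Hbb were each separated between all 6 and 6 arrays, as the rule for naming them required.

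Gene groups differed between the ages in both directions. Of 12 interferon response genes 9 were higher in adults, and 11 when adjusted over the list alone (median 1.16 log2, or 0.68 log2 with values under the filter level raised to it, camera adjusted p = 8.5e-10, adjusted p = 0.0282 with an estimated correlation). Ifi27l2b was higher by 2.06 log2, Ifi27 by 1.28 log2, Ifitm3 by 1.15 log2 and Stat2 by 0.83 log2, but by 0.09 log2 in its other probe set (adjusted p = 0.635). In the MHC class I list 6 of 10 were higher, and 7 when adjusted over the list alone (median 0.57 log2, camera adjusted p = 3.0e-05, adjusted p = 0.0289 with an estimated correlation). RT1-S3 was higher by 1.37 log2, or 0.83 log2 in its other probe set, and B2m by 0.59 log2. Reactive astrocyte genes had 6 of 14 higher and 1 lower, and 7 higher and 1 lower adjusted over the list alone (median 0.34 log2, camera adjusted p = 3.1e-04, adjusted p = 0.0453 with an estimated correlation). Fgl2 was higher by 1.94 log2, Tm4sf1 by 1.17 log2 and Gfap by 0.36 log2. Oligodendrocyte precursor genes were lower in 5 of 9 cases, and 6 adjusted over the list alone (median -0.47 log2, camera adjusted p = 3.1e-04, adjusted p = 0.0289 with an estimated correlation). Tnr had a difference of -1.02 log2 and the growth factor receptor Pdgfra of -0.68 log2. Genes of immature neurons and axon growth were lower in 12 of 31 cases and higher in 2, and 13 lower and 2 higher adjusted over the list alone (median -0.25 log2, camera adjusted p = 4.5e-04, adjusted p = 0.0475 with an estimated correlation). Doublecortin, Dcx, had a difference of -1.28 log2 and Marcks of -0.82 log2, or -0.96 to -1.49 log2 in its other probe sets, whereas the axonal adhesion molecule Cntn2 was higher by 1.85 log2.

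Other lists passed camera between sham groups but not with an estimated correlation. Microglia and macrophage genes had 8 of 27 higher, and 11 higher and 1 lower adjusted over the list alone (median 0.29 log2, or 0.14 log2 with values raised to the level, camera adjusted p = 3.0e-05, adjusted p = 0.0798 with an estimated correlation), with the lysozyme Lyz2 at 1.51 log2. Complement had 5 of 10 higher and 1 lower under both adjustments, over all genes and adjusted over the list alone (median 0.60 log2, camera adjusted p = 8.6e-04, adjusted p = 0.149 with an estimated correlation). MHC class II genes had 3 of 8 higher, and 3 adjusted over the list alone (median 0.41 log2, camera adjusted p = 0.00145, adjusted p = 0.162 with an estimated correlation). Fibroblast and matrix genes had 13 of 39 lower and 2 higher, and 13 lower and 3 higher adjusted over the list alone (median -0.36 log2, camera adjusted p = 0.00153, adjusted p = 0.528 with an estimated correlation). The laminin chain Lamc1 had a difference of -1.22 log2 and the collagen chain Col4a1 of -1.18 log2. Excitatory neuron genes had 4 of 19 lower and 1 higher, and 7 lower and 1 higher adjusted over the list alone (median -0.33 log2, camera adjusted p = 0.0151, adjusted p = 0.528 with an estimated correlation). Immediate-early genes had 5 of 15 lower, and 6 adjusted over the list alone (median -0.38 log2, camera adjusted p = 0.0460, adjusted p = 0.177 with an estimated correlation). Motor neuron genes had a median of 0.87 log2, with 1 of 10 higher over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0434, adjusted p = 0.572 with an estimated correlation). Without adult sham 4 the median of motor neuron genes was 0.33 log2, and the camera adjusted p of excitatory neuron, immediate-early and motor neuron genes was 0.113, 0.0785 and 0.138. Slc17a6 was lower in adults by a difference of -0.27 log2 (adjusted p = 0.0221), but had adjusted p of 0.0531, 0.0646 and 0.0503 without adult sham 4, 5 and 6.

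All 4 measured red blood cell genes were higher in adult sham, over all genes and adjusted over the list alone, with a median of 2.51 log2. The list was too short for the set test. The anion exchanger Slc4a1, at 0.30 log2, had adjusted p between 0.0510 and 0.0725 without adult sham 1, 2 or 5 or neonate sham 1 or 5. In both injury comparisons 0 of the 4 passed limma's test, and 0 had an unadjusted p under 0.05. The mean over the 4 genes was 9.93 and 9.67 log2 in adult sham and SNI, and 7.55 and 7.80 log2 in neonate sham and SNI. In total 1573 probe sets differed between sham groups, 724 higher and 849 lower in adults, and 806 had no overlap between the 6 and 6 arrays (chance share 0.216%). The split was 831 higher and 757 lower after quantile normalization, 768 and 776 after median centring of each array, and 680 and 945 without the arrays numbered 3.

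**Figure D4:**
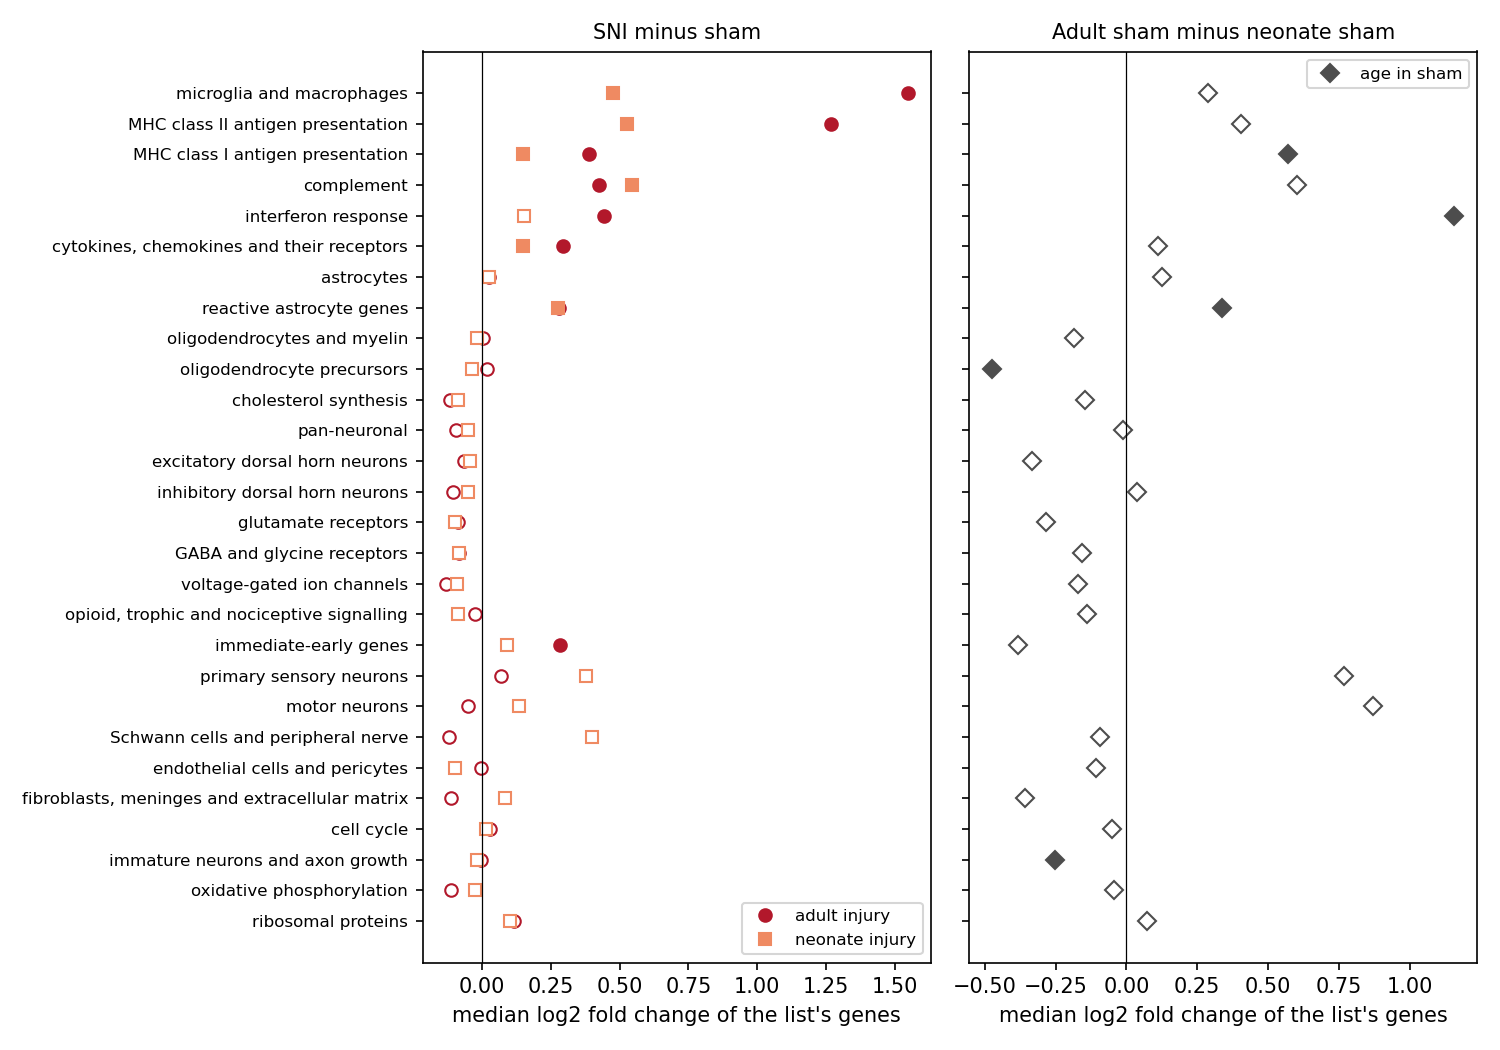
Median log2 change of the 28 gene lists with at least 5 measured genes in adult injury (circles), neonate injury (squares) and adult against neonate sham (diamonds). Filled marks passed camera with the preset and with an estimated correlation, open marks did not. The microglia list had medians of 1.55, 0.47 and 0.29 log2.

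Lymphocyte genes were mostly below detection. Of 34 named T cell genes 4 passed the filter and 27 lay below the filter level on every array. Of the 4, Rac2, a GTPase of blood cells, was at least 2.31-fold higher in adult SNI (adjusted p = 1.3e-08) and the actin-binding protein Coro1a rose by 0.92 log2 (adjusted p = 8.5e-05). Cd48, an adhesion molecule of leukocytes, rose by 0.73 log2 (adjusted p = 0.0376), but had adjusted p of 0.0623 to 0.120 without adult sham 2, 4, 5 or 6 or adult SNI 1, 3, 5 or 6. In total 3 of the 4 rose in adults, over all genes and adjusted over the list alone, and 0 in neonates by either count in limma, against 2 at an unadjusted p under 0.05. The difference between the ages passed for Rac2 (adjusted p = 8.7e-04), which lay below the filter level on all neonate arrays, and not for Coro1a (0.58 log2, adjusted p = 0.756). The 1 named B cell gene, Cd79b, did not pass the filter, and of 18 neutrophil and mast cell genes 1 did, S100a9, with differences of -0.57 and -0.03 log2 in adults and neonates (adjusted p = 0.897 and 1). Among index genes chosen in advance that the filter removed, the T cell receptor component Cd3e had 2.36 log2 in adult SNI and 2.21 in sham (exact permutation p = 0.357, adjusted p = 0.595 over 10 tests), and Cd3d and Cd2 had the same value on all arrays. Cd4, also in the T cell list, was higher in adult SNI, at 3.77 against 2.21 log2 in sham (exact permutation p = 0.0043, adjusted p = 0.0216). It lay above the filter level on 3 of 6 adult SNI arrays. Which cells carried Cd4, Rac2, Coro1a and Cd48 was not tested. As Cd3d, Cd3e and Cd2 were not shown to rise, these values do not establish a T cell signal.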

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

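The tests of the floor of the values, of RNA integrity, of dilution over all 139 genes and of list means between ages, and the list without Cxcl13, were chosen only after the results had been seen. Exact tests were two-sided.

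The injury effect differed with age, by limma's test of the difference, for 22 probe sets. The fitted differences (adult minus neonate) were 5.15 log2 for Cxcl13, 3.48 for Fcgr3a, 2.44 for Ly86, 2.42 for Fcgr2b, 2.19 for Plac8, 2.14 for Irf8, 2.14 for Serpinb1a, 1.94 for Clec4a3, 1.86 for Tspo, 1.55 for Cd37, 1.40 for Rac2 and 1.29 for Pycard. Of the 22, 8 lay below the filter level on all neonate arrays and Plac8 on all neonate sham arrays, and 9 lay at or above it on all 24 arrays. The fitted sizes and the tests of the 8 and of Plac8 depend on the background model. By exact permutation the mean rise also differed for the microglia list, by 0.87 log2, and for the list of cytokines and their receptors, by 0.55 log2 (both p = 0.0022, adjusted p = 0.0303 over 28 lists). Without Cxcl13, which lay at the floor on every neonate array, the cytokine list differed by 0.28 log2 (exact permutation p = 0.0043). This p was not adjusted over the lists, so a larger adult rise of the cytokine list without Cxcl13 is not established. The floor was not tested for the other cytokine genes.

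The larger adult rise of the microglia list could come from weaker activation in neonates, from the floor of the values, or from neonate tissue mixed with more unaffected tissue. Over the 16 list members at or above the filter level on all 24 arrays, the rise was 1.26 log2 in adults and 0.69 log2 in neonates, a difference of 0.57 log2 (95% interval 0.33 to 0.82, exact permutation p = 0.0022, against 0.205 in the test first run, whose reference held the injury effects). A floor below the level therefore cannot alone account for the difference of these genes, while a floor of single probe sets above it was not tested. The other 11 exceeded it by 0.74 log2, or 0.55 log2 with values raised to the level, and for them a hidden neonate rise and a weaker response cannot be told apart, since values under the level are not resolved. Under a single dilution factor about 5%, and under 15%, of the genes above the level were foreseen outside the 95% range. Of these 106 genes 4 (3.77%) lay outside it (best factor 0.32), as dilution foresaw. A response weaker by the same factor in all genes would give the same result, so this result does not favour dilution over weaker activation. Among all 139 genes higher in adults, a set chosen after the results had been seen, 14.4% did (20 genes at a best factor of 0.23, 15 at 0.32). Of the 20, 9 lay below the range, Serpinb1a, Cxcl13 and Fcgr3a among them, and 11 above it, C3 among them. These genes are not independent. Most of those below the range lie near the floor, while most of those above it were measured at or above the level. Dilution therefore remains open.

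The interferon, MHC class I, MHC class II and complement lists passed camera as higher in adult sham, the last 2 not with an estimated correlation, and red blood cell genes were higher too, so blood left in the tissue could contribute. With the red blood cell score as a covariate the age difference of the 39 genes of these 4 lists was 0.54 log2 (95% interval 0.11 to 0.96), against 0.87 log2 (0.65 to 1.08) without it. The interval stayed above 0, but the fit held the group means, so the slope (0.139, SE 0.0745) rested on scatter within groups. Error in a score of few genes would lower that slope. The fit therefore cannot decide how much of the difference is owed to blood. Age itself is the biological explanation that the design offers, and a shift in the share of other cell types was not tested.

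Arrays of the same number deviated together, and the 4 arrays numbered 3 lay apart from the rest, with a mean correlation of 0.551 among themselves. RNA integrity might be the cause: their actin 3' minus 5' difference was higher than that of the others by 0.29 log2, in all 4 groups. The Gapdh difference was -0.018 log2, lower in 3 of the 4, so RNA integrity remains open, and no biological explanation was tested because the labels do not say what a number stands for.

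Other ways of splitting the arrays served to test whether calls of this number arise by chance. In adults 1 of 100 splits, the real one, gave as many as 193 calls (highest other 74). Between sham groups 1 of 100 gave 1573 (highest other 836), and for the difference between ages 1 of 100 joint splits gave 22 (highest other 13). The joint splits exchange injury labels within an age, so their reference holds the injury effects and they do not test equal effects at both ages. In neonates 2 of 100 gave 30 or more, since 1 other split, which kept the arrays numbered 1 and 4 together against 3 and 6, gave 289. Among the 32 neonate splits that part all 6 pairs, the highest other count was 15.

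Single arrays stood far from the 5 others of their group in 14 of 261 groups tested, where chance alone gives about 5%. Adult sham 3 had 5.73 log2 for the microglia list (others 5.95), 5.52 for the interferon list (6.05), 6.47 for C3 (8.34) and 5.23 for Dpysl4 (6.54). Adult SNI 3 had 0.882 log2 for the actin 3' minus 5' difference (0.603), and neonate sham 3 had 7.16 for the Schwann cell list (8.75). Neonate SNI 1 had 9.25 log2 for the GABA and glycine receptor list (9.74), and adult sham 4 had 6.93 for the endothelial list (6.66) and 4.51 for Serpinb1a (4.68). C3 was 10.43 log2 on adult SNI 5 (11.33), and Serpinb1a was 5.10 on neonate SNI 4 (4.73). Tspo was 7.09 log2 on adult sham 1 (5.88) and 4.79 on neonate sham 5 (5.61), and Mbp was 15.22 on adult sham 1 (14.94).

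Among genes that the filter removed, signals stood above sham in adult SNI. The lysosomal macrophage protein Cd68 averaged 4.93 ± 0.85 log2 (SD, n = 6) against 2.09, at least 2.13-fold, above the filter level on 5 of 6 arrays (exact permutation p = 0.0022, adjusted p = 0.0216 over 10 tests). Cd4 averaged 3.77 ± 0.79 log2 against 2.21 ± 0.21 (SD, n = 6, exact permutation p = 0.0043, adjusted p = 0.0216), and the chemokine Ccl2 averaged 3.78 ± 1.44 log2 against 2.11 (exact permutation p = 0.0152, adjusted p = 0.0433), each above the level on 3 of 6 arrays. The index gene Itgam had 3.08 against 2.66 log2 (exact permutation p = 0.0173, adjusted p = 0.0433), but on 0 of 6 adult SNI arrays above the level. In neonate SNI, Cd68, Cd4 and Ccl2 averaged 2.17, 2.17 and 2.25 log2, each above the level on 0 of 6 arrays.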

How the results depend on the processing

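Of 505 fold changes of named genes, 167 of them called, none reversed in the alternatives that covered it (32 of 35 covered all 505, the others at least 372), where those called in neither fit were counted as unchanged whatever their sign. Calls did change: 2 were lost and 26 gained with the replicate block, and 2 lost and 11 gained with the age-specific block. In the order adult injury, neonate injury, difference between ages and age in sham, leaving out single arrays gave 169 to 200, 23 to 31, 19 to 29 and 1248 to 1658 probe sets, and 12 to 17, 13 to 17, 11 to 13 and 9 to 14 lists. The filter at the 60th percentile left 106 probe sets in adults and 6 for the difference between ages, as fewer dim probe sets were tested. Requiring a log2 change of at least 1 left 85, 18 and 207 in adults, neonates and sham groups, by its construction. Only the 12 arrays of the comparison gave 18 in neonates, with fewer arrays for the variance. The replicate block gave 297 in adults and 2468 in sham groups, the age-specific block, chosen after seeing the data, 291 in adults, and neither moved another count by over 1.5 times. Without the arrays numbered 3, an alternative also chosen after seeing the data, 10 lists passed in neonates (16 with all arrays), with fewer arrays. With the correlation estimated 8, 6, 5 and 5 lists passed, and with fry 9, 4, 2 and 14, and the cause was not tested. The correlation of adult and neonate effects ran from 0.459 without neonate SNI 3 to 0.597 without neonate sham 3, and the cause was not tested. A transformation planned for linear values was not run. Signal near the background limits what the arrays show, since differences among values below the filter level are not resolved.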

Other observations

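Genes of support cells differed between adult and neonate sham even where their lists as a whole did not pass camera. Among oligodendrocyte and myelin genes, 4 of 22 were higher and 6 lower in adults, and 5 higher and 6 lower adjusted over the list alone (median -0.19 log2 and mean -0.03 log2, camera adjusted p = 0.351). The pteridine reductase Qdpr was higher by 1.56 log2 (SE 0.11, adjusted p = 3.3e-10), while the cell adhesion molecule Nfasc had a difference of -1.07 log2 (SE 0.097, adjusted p = 2.5e-08), but -0.01 and -0.07 log2 in its other probe sets (adjusted p = 0.970 and 0.868). Among astrocyte genes 4 of 27 were higher and 2 lower by both counts, over all genes and adjusted over the list alone (median 0.13 log2, camera adjusted p = 0.0685). The calcium-binding protein S100b was higher by 0.85 log2 (SE 0.13, adjusted p = 3.3e-05) and Scrg1 had a difference of -1.09 log2 (SE 0.13, adjusted p = 2.6e-06).

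Vessel and synapse genes also moved in both directions. Endothelial and pericyte genes had 2 of 24 higher and 5 lower, and 2 higher and 8 lower adjusted over the list alone (median -0.11 log2, camera adjusted p = 0.757). The blood-brain barrier transporter Slco1a4 was higher in adults by 1.76 log2 (SE 0.13, adjusted p = 1.2e-09), or 2.86 log2 in its other probe set. Glutamate receptor genes had 1 of 21 higher and 3 lower, and 1 higher and 4 lower adjusted over the list alone (median -0.28 log2, camera adjusted p = 0.151). The synaptic scaffold Homer1 had a difference of -0.82 log2 (SE 0.16, adjusted p = 8.4e-04).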
